A study of Mus musculus and Homo sapiens with 4 samples.

How the data were processed

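Ribosome profiling was done on 4 libraries: E14 mouse ES cells treated with cycloheximide or with emetine, and HEK cells before (input) and after (bound) capture of tagged ribosomes. Per the labels' protocols, lysates were digested with RNase I. Ribosomes were pelleted in the mouse samples and separated by size exclusion chromatography in the HEK samples. Footprint RNA was then ligated to a linker, reverse transcribed, circularized and amplified by PCR. The labels name no molecular identifiers, and amplified copies of one footprint are not independent molecules, so intervals and floors cover counting error only. Nothing in the labels says whether the libraries of a pair came from the same culture or lysate.

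The deposited values are raw read counts per transcript and per part of it, with 1 file per library, made by the authors. Per the file headers the columns are the whole transcript, the coding region, the 5' leader and the 3' trailer. CASAVA 1.8, Bowtie2 2.0.6 and TopHat2 2.0.7 and the builds mm10 and hg19 are named, without a role, in the submitters' processing notes. The counting tool, the annotation release, the treatment of reads with several matches and the exact bounds of the parts are not given in the sources used here. In transcripts with all 3 parts the parts sum to less than the whole transcript, so some reads lie in none of them. The files give no coordinates, lengths or fragment sizes, so footprint positions and lengths were not analysed here, and neither was density per base.

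A part was taken as present where neither library of a pair lists it as missing, because transcripts with 0 reads list 0 for parts they lack. Each transcript gave 1 feature: its coding region, or the whole transcript where no coding region is counted. The choice of 1 transcript per gene that had been planned could not be made. Of 93380 mouse and 194871 human transcript identifiers, 0 occur in the name tables used here. For the same reason the 36 gene lists fixed before the data were examined, the comparison of genes across species, the separation of mitochondrial genes and most of the planned naming of genes were not run. Of the planned rule, which named more at each end and members of the lists, the 2 highest and 2 lowest features per comparison are kept, by log2 ratio among features with at least 100 summed reads. Isoforms overlap, so features were not treated as independent; 1905 of 57672 mouse and 8516 of 48823 human features compared repeat another transcript's counts exactly.

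Ratios are of emetine over cycloheximide and of bound over input. The count scale of each pair was set so that the median log2 ratio of coding regions with at least 100 summed reads is 0. The coding-region counts of the mouse libraries differed 1.76-fold in depth by this measure and those of the HEK libraries 1.99-fold. A prior of 0.5 scaled reads was added before taking log2. With 1 library per group no test of the conditions exists and no p-value is given. Each named ratio with reads in both libraries has an exact (Clopper-Pearson) two-sided 95% counting interval. A count of 0 has no such ratio and was set against a floor of 3 reads in that library, about the one-sided 95% limit of a count of 0; a two-sided interval would begin lower. Leaders and trailers were compared with the coding region of the same transcript, which does not depend on the scaling; medians carry a 95% interval from ranks, which treats transcripts as independent and is therefore too narrow. A class of features was also set against 10000 random lists of coding regions of the same size and matched on summed reads in bins of 0.5 log2 units, as a description of these libraries. The lists also treat features as independent, so the spread of their medians is too small. Counting error alone was simulated by splitting each summed count binomially at the scaled depth.

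Features at least 2-fold different were counted in each direction. Alternatives were scaling to total counts, edgeR's TMM scaling, minimums of 30 and 500 summed reads or 1 read in each library, priors of 0 and 5, whole transcripts in place of coding regions, and thresholds of 1.5-fold and 4-fold. These were fixed before the data were examined. For leaders and trailers against their own coding region, the minimum of 1 read was instead applied to reads summed over the pair in each part. Counting identical rows once, thinning the deeper library of each pair, and leaving out the 10 most abundant features from shares were added after seeing the data, as were the counts of different pairs of counts. Alternative medians of matched lists used fewer random lists, and with a minimum of 30 reads all features under 100 reads fell in 1 matching bin. Data were simulated with 200 features changed 4-fold or 8-fold in each comparison and counting error as the sole noise. At the 2-fold threshold all changes of the 193 compared in the mouse pair and of the 164 compared in the HEK pair were called (100%). Changes near 2-fold were not simulated, so this does not show how well those are called. With 57644 mouse and 48818 HEK features compared, changed ones included, 0.0017% and 0.010% of the unchanged features were called. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.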

Results

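Ribosome footprints were sequenced from 4 libraries that form 2 pairs. A ribosome footprint is the short piece of RNA that a ribosome shields from nuclease digestion, so counting footprints along a transcript shows where ribosomes sit. The first pair came from E14 mouse embryonic stem cells (ES cells), grown without feeder cells and with LIF, a cytokine that keeps such cells undifferentiated. One library came from cells exposed to cycloheximide at 100 µg/ml for 60 s and the other from cells exposed to emetine for 60 s; both drugs arrest ribosomes during elongation. The second pair came from HEK cells, a human embryonic kidney line, grown in medium with 10% serum. One HEK library was made without capture (input). The other held assembled ribosomes captured on streptavidin through an affinity tag on the large subunit (bound). Each group had 1 library, so no p-value across transcripts was computed, and every comparison below is between libraries. Intervals cover at most counting error, not variation between cultures.

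The reads counted for transcripts summed to 342552347 with cycloheximide, 188700177 with emetine, 17446956 in the HEK input and 30208713 in the bound library. Many transcripts repeat the counts of another and the counting rule is not given in the sources used here, so these sums were not taken as the number of reads, and the true depth is unknown. Coding regions held 163107357, 78702902, 7631840 and 15411358 of these counts, in the same order. The mouse files list 93380 transcripts, 43857 of them with a coding region, and the human files list 194871, of which 75470 have one. Transcripts were identified by Ensembl transcript identifiers. The files and the name tables used here do not pair these with gene names, so results are given for parts of transcripts. These parts are the coding region, the 5' leader and the 3' trailer (the untranslated parts before and after it). Transcripts for which no coding region was counted form a class of their own, which can hold noncoding RNA as well as noncoding isoforms of coding genes. Isoforms overlap, so some reads of this class may also be counted for coding regions. Ratios were scaled so that the median coding region had a log2 ratio of 0, and features with at least 100 reads summed over a pair were compared.

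The bound and input libraries address whether footprints travel with the tagged large ribosomal subunit. Coding regions kept nearly the same proportions in the bound library. The scaled median absolute deviation of their log2 ratios was 0.25 over 26492 coding regions, against 0.15 from counting error alone. At the main scaling the 2-fold differences went mostly one way. In the bound library 228 coding regions (0.86%) were at least 2-fold lower and 14 (0.053%) at least 2-fold higher. Among 22331 transcripts without a coding region, 577 (2.58%) were at least 2-fold lower and 41 (0.18%) at least 2-fold higher. Counting error alone gave 2 lower and 7 higher in that class, and 0 lower and 2 higher among coding regions. Scaling to total counts shifted all HEK ratios up by 0.20, and the calls became 216 higher and 574 lower, in place of 55 and 805. Coding regions were then closer to balance, with 87 higher and 131 lower. Transcripts without a coding region had 129 higher and 443 lower.

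The body of the class without a coding region had ratios like those of coding regions in this purification, and its difference lay in a long low tail. Where isoforms overlap, part of this likeness may come from the same reads. Its median log2 ratio was 0.0043, which is 0.013 above that of coding regions with the same number of reads. That median lay above all of 10000 random count-matched lists of coding regions, whose medians ran from -0.012 to -0.0048 in the central 95%. The lists treat features as independent although isoforms overlap, so this range is too narrow. The difference was -0.0013 with a minimum of 30 reads and 0.044 against whole coding transcripts. In the tail, 191 of these transcripts were at least 4-fold lower, 130 at least 8-fold lower and 88 at least 16-fold lower. For coding regions the matching numbers were 32, 9 and 5. No feature of either class was 4-fold higher. The 577 lower transcripts were chosen by their ratio, so their share had to fall. They held 32.2% of the reads of their class in the input and 4.01% in the bound library. Without the most abundant of them these shares were 16.6% and 2.02%. The 228 lower coding regions, chosen likewise, held 0.997% and 0.149% of the reads of theirs.

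The share of lower transcripts did not rise steadily with abundance, and it was highest among abundant transcripts. It was 3.15% of 12315 transcripts from 100 to under 300 reads and 1.36% of 6906 from 300 to under 1000 reads. From 10000 to under 100000 summed reads, 19 of 115 transcripts without a coding region (16.5%) were at least 2-fold lower in the bound library, against 2 of 197 coding regions (1.02%). From 1000 to under 10000 reads the numbers were 74 of 2991 (2.47%) and 6 of 4395 (0.14%). The transcript with the most reads of this class took 7.77% of all counts in the input (1355851 reads) and 0.71% in the bound library (215008 reads); it was singled out after its values were seen. The class as a whole took 44.3% of counts in the input and 37.7% in the bound library. Without its 10 most abundant transcripts it took 37.3% and 36.4%. Some abundant transcripts have nearly equal counts. With both counts rounded to 2 significant digits, the 19 lower transcripts formed 17 of 99 different pairs of counts, against 2 of 109 for coding regions in that bin. Over all bins the 577 formed 461 of 4772 pairs, against 164 of 4317 for coding regions.

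**Figure D1:**
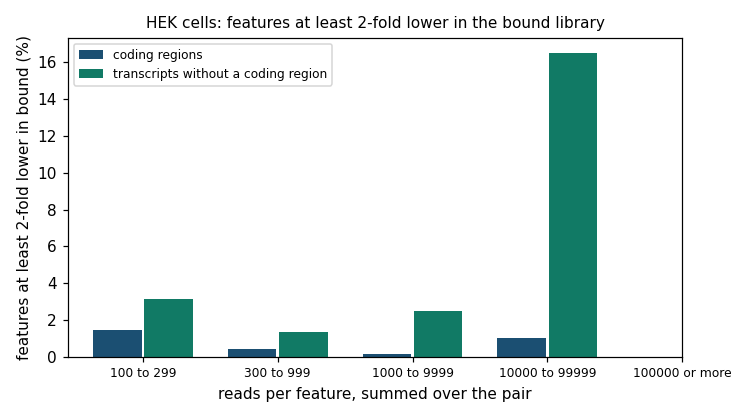
Percentage of HEK features at least 2-fold lower in the bound than in the input library (y axis) by reads summed over the pair (x axis), for coding regions and for transcripts without one. Bins with fewer than 20 features are left out, so the bin of 100000 or more reads is empty; the bar for 10000 to under 100000 reads reaches 16.5% for transcripts without a coding region and 1.02% for coding regions.

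The 2 lowest ratios of the HEK pair among features with at least 100 reads were found in transcripts without a coding region. ENST00000411193.1 had 1540 reads in the input and 6 in the bound library, a ratio 510-fold lower (95% exact counting interval 234 to 1393). ENST00000413558.1 had 118 reads in the input and 0 in the bound library. Against a floor of 3 reads it was at least 78.2-fold lower; another transcript has the same counts. The highest ratios belonged to coding regions with few reads. The coding region of ENST00000370210.1 had 18 input and 103 bound reads, 2.88-fold higher (interval 1.73 to 5.05). That of ENST00000550765.1 had 15 and 85 reads, 2.85-fold higher (interval 1.63 to 5.31).

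Among parts with at least 100 reads, leaders were slightly lower than the coding region of the same transcript after capture, and trailers were close to it. Over 930 transcripts with enough reads in both parts, the 5' leader's log2 ratio was lower than that of its own coding region by a median of 1.16-fold (median difference -0.21, 95% interval -0.24 to -0.17). The difference was above 0 in 295 of them (31.7%). It shrank to -0.055 in parts with at least 500 reads. For 1687 transcripts with a measured 3' trailer the median difference was -0.0052 (interval -0.023 to 0.020), and 49.4% lay above 0. With a minimum of 1 read summed over the pair in each part, the trailer difference was -0.47 and the leader difference -0.29. That minimum admits parts with no reads in 1 library, whose ratios depend on the prior and the depth. Taken as a class, leaders had a median log2 ratio of -0.14, below all 10000 count-matched lists of coding regions. Scaled to total counts the leader median was 0.062 and the coding median 0.20; this scaling shifts every ratio alike and cannot change the gap between them. Leaders took 5.39% of the reads of the 3 parts in the input (95% exact binomial interval 5.37 to 5.40) and 2.85% in the bound library (2.84 to 2.85). These intervals take summed counts as separate reads although many transcripts repeat the counts of another, so they are too narrow even for counting error. Most of this difference lay in a few leaders: without the 10 most abundant features of each part the shares were 2.93% and 2.38%. The 5 leaders with 10000 or more reads were each at least 2-fold lower in the bound library, a group chosen after its values were seen.

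The cycloheximide and emetine libraries address whether footprints shift with the drug that arrests the ribosome. With emetine, reads outside coding regions were more frequent relative to reads inside them. The 5' leader was higher than its own coding region by a median of 1.31-fold over 10499 mouse transcripts (median log2 difference 0.39, 95% interval 0.38 to 0.41). It was above in 7445 of them (70.9%), and 2009 leaders were at least 2-fold higher against 359 at least 2-fold lower. The 3' trailer was higher than its own coding region by a median of 1.19-fold over 5467 transcripts (0.25, interval 0.22 to 0.27), with 63.7% above 0. In parts with at least 500 reads the leader difference was 0.47 and the trailer difference 0.016. With at least 1000 reads the leader difference was 0.53 (1959 transcripts) and the trailer difference was -0.053 (1618 transcripts). From the lower to the upper quartile of trailer reads per coding read the trailer difference went from 1.11 to -0.12. Leaders took 3.03% of the reads of the 3 parts with cycloheximide (95% exact binomial interval 3.03 to 3.04) and 4.55% with emetine (4.55 to 4.56). As in the HEK pair, these intervals are too narrow even for counting error. Trailers took 4.79% and 5.54%, and coding regions 92.2% and 89.9%.

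**Figure D2:**
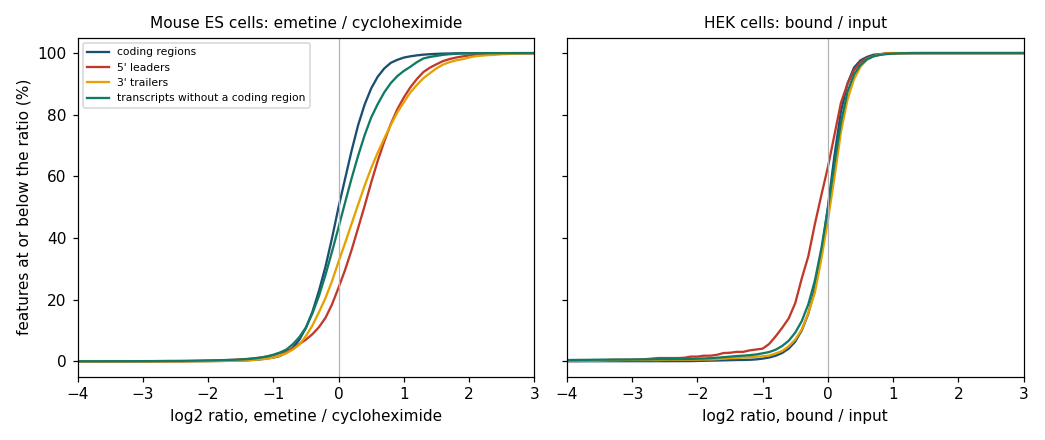
Cumulative percentage of features (y axis) at or below each log2 ratio (x axis) for coding regions, 5' leaders, 3' trailers and transcripts without a coding region, with emetine over cycloheximide in mouse ES cells at left and bound over input in HEK cells at right. Leaders lie to the right of coding regions in the mouse pair (median 0.39) and to the left in the HEK pair (median -0.14; scaled to total counts it was 0.062, against 0.20 for coding regions).

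The coding regions themselves spread more between the inhibitors than counting error gives. The scaled median absolute deviation of their log2 ratios was 0.41 over 28604 coding regions, against 0.059 from counting error alone. Across coding regions the read numbers of the mouse libraries had a Spearman correlation of 0.985, and those of the HEK libraries 0.964. These are correlations across features, which are not independent replicates. With emetine 418 coding regions (1.46%) were at least 2-fold higher and 341 (1.19%) at least 2-fold lower. Counting error alone gave 0 and 2. The balance depended on the settings: TMM scaling gave 348 higher and 397 lower, total counts 511 and 294, a minimum of 30 reads 918 and 944, and a 4-fold threshold 9 and 16.

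The ratio between the inhibitors moved with the abundance of the coding region. Scaling to total counts shifted all mouse ratios up by 0.047 and TMM scaling shifted them by -0.045, so values are relative to the median coding region. The median log2 ratio was 0.11 for 3691 coding regions with 100 to under 300 summed reads and 0.028 for 14510 with 1000 to under 10000 reads. It was -0.18 for 4352 with 10000 to under 100000 reads. For 250 coding regions with 100000 or more reads it was -0.52, a level 1.43-fold lower with emetine, with quartiles at -0.62 and -0.37. Trailers followed a similar course, from 0.56 at 100 to under 300 reads to -0.23 at 10000 to under 100000 reads. Leaders did not: their medians were 0.38, 0.41, 0.40 and 0.38 in the successive bins up to under 100000 reads.

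**Figure D3:**
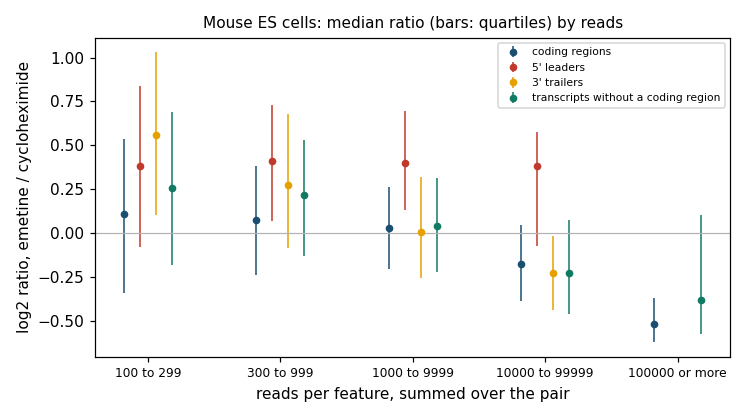
Median log2 ratio of emetine over cycloheximide in mouse ES cells (y axis; points are medians, bars run from the lower to the upper quartile of features) by reads summed over the pair (x axis), for the 4 classes. Bins with fewer than 20 features are left out; coding regions run from 0.11 to -0.52, while leaders stay between 0.38 and 0.41.

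Transcripts without a coding region were more often higher with emetine than coding regions were. Among 29068 of them, 1688 (5.81%) were at least 2-fold higher and 616 (2.12%) at least 2-fold lower, while counting error alone gave 0 of each. At larger differences the direction turned: 28 were at least 4-fold higher and 83 at least 4-fold lower, and 1 was at least 8-fold higher and 14 at least 8-fold lower. Their median log2 ratio was 0.082, which is 0.061 above count-matched coding regions and above all 10000 random lists. Measured against whole coding transcripts in place of coding regions this difference was -0.00052. The share that was higher was 12.1% (625 of 5184) from 100 to under 300 reads, against 7.37% of coding regions (272 of 3691). It differed more from coding regions among abundant members, although their median ratio was -0.23 from 10000 to under 100000 reads, against -0.18 for coding regions. From 10000 to under 100000 reads, 270 of 3193 (8.46%) were at least 2-fold higher with emetine, against 4 of 4352 coding regions (0.092%). At 100000 or more reads the numbers were 24 of 267 (8.99%) and 1 of 250 (0.40%). Many of these have nearly equal counts, and at 2 significant digits the 270 formed 100 of 1693 different pairs of counts, against 4 of 1713 for coding regions. The most abundant transcript of the class took 0.68% of all counts with cycloheximide (2321590 reads) and 2.24% with emetine (4223386 reads). The class as a whole took 44.3% and 48.5% of counts. Without its 10 most abundant transcripts it took 42.9% with cycloheximide and 45.8% with emetine.

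The 2 highest ratios in mouse ES cells among features with at least 100 reads were found in transcripts without a coding region. ENSMUST00000174979 had 14 reads with cycloheximide and 114 with emetine, 14.3-fold higher (95% exact counting interval 8.19 to 27.0). ENSMUST00000181460 had 21 and 90 reads, 7.53-fold higher (interval 4.64 to 12.8). The lowest belonged to the same class. ENSMUST00000156514 had 103 reads with cycloheximide and 0 with emetine, at least 19.5-fold lower against a floor of 3 reads. ENSMUST00000133716 had 102 and 0 reads, at least 19.3-fold lower, and another transcript has the same counts.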

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

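In mouse transcripts with all 3 parts, 10.3% of the reads with emetine lay in none of the parts, against 7.66% with cycloheximide. This drew attention because the comparisons of parts in the report do not use these reads, which enter only values for whole transcripts and total counts, and their share was above that in the cycloheximide library. Measured against its own coding region, this remainder was higher with emetine in 10837 of 14600 transcripts (74.2%), by a median of 1.33-fold. In the HEK pair it was 5.68% in the input and 5.32% in the bound library, and 33.2% of 2370 transcripts lay above 0.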

How the results depend on the processing

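Thinning the deeper library and counting identical rows once were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The median differences that the report gives as above 0 for leaders and trailers with emetine, and below 0 for leaders in the HEK pair, kept their sign under the alternatives given here. For trailers this does not extend to a minimum of 1000 reads, where the difference was -0.053. The longest transcript per gene, random lists of nuclear-encoded genes and matching on coding length were planned and not run, because the transcripts could not be paired with genes or lengths. In the HEK pair 1048 leaders had 100 or more reads, against 10677 in mouse, so its leader values rest on fewer features. A median was taken as moved when it left the 95% interval of the main median.

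In the mouse pair 2106 features were at least 2-fold higher and 957 lower. With a minimum of 30 reads these were 3365 and 2068, with 500 reads 905 and 349, and with 1 read in each library 5324 and 2921. A 1.5-fold threshold gave 7320 and 4531, and a 4-fold threshold 37 and 99. The spread of coding regions, 0.41, was 0.44 with 30 reads, 0.37 with 500, 0.46 with 1 read in each library and 0.37 for whole transcripts. The leader difference was 0.47 with 500 reads, 0.28 with 1 read summed over the pair and 0.42 with the cycloheximide library thinned. The trailer difference was 0.43 with 30 reads, 0.016 with 500 reads and 0.22 after thinning. The difference of transcripts without a coding region from count-matched coding regions, 0.061, was 0.070 with 30 reads, 0.029 with 500 reads and -0.00052 with whole transcripts.

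In the HEK pair 55 features were at least 2-fold higher and 805 lower. With 30 reads these were 817 and 3162, with 500 reads 0 and 144, and with 1 read in each library 3982 and 12072. A 1.5-fold threshold gave 869 and 2726, and a 4-fold threshold 0 and 223. The number higher was 216 when scaled to total counts, 104 with TMM scaling, 31 with a prior of 5 and 19 with the bound library thinned. The spread, 0.25, was 0.32 with 30 reads, 0.17 with 500, 0.41 with 1 read in each library, 0.24 with a prior of 5 and 0.24 after thinning. The leader difference was -0.27 with 30 reads, -0.055 with 500 reads and -0.29 with 1 read summed over the pair. The trailer difference was -0.47 with 1 read summed over the pair. The difference of transcripts without a coding region, 0.013, was -0.0013 with 30 reads (with the same coarser matching), 0.026 with 500 reads and 0.044 with whole transcripts. For these changes the cause was not tested, except that a lower or higher minimum changes which features are compared.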

Other observations

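The comparison of low leaders and trailers with their coding regions, that of leaders by abundance, and the test of the HEK scaling, which replaced one whose outcome was fixed in advance, were chosen after the results were seen. The 3 patterns weighed here were found in these data first, and the bounds for their other tests were set after the patterns and before the test values were seen. In the HEK pair 43 leaders were at least 2-fold lower in the bound library. Of the 26 whose coding region could be compared, 19 had a coding region that was not 2-fold lower. The median log2 ratio of these coding regions was -0.30, and over all HEK coding regions compared 0.86% were 2-fold lower. Coding regions of low leaders were thus 2-fold lower more often than coding regions at large. Of 68 trailers at least 2-fold lower, 20 had a coding region that could be compared, and in 18 of them it was not 2-fold lower. The median log2 ratio of the coding regions of low trailers was -0.13. HEK coding regions showed a weak trend with abundance, from a median log2 ratio of -0.061 at 100 to under 300 reads to 0.13 at 10000 to under 100000 reads.

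In HEK cells, transcripts without a coding region held a larger share of features 2-fold lower after capture than coding regions did. With whole transcripts in place of coding regions, 351 coding transcripts and 556 without a coding region were 2-fold lower. The main numbers were 228 and 577, so the gap in counts was smaller for whole transcripts. Counting error alone gave 2 such transcripts in place of 577, which argues against it. Counting identical rows once left 3.40% against 0.855%, a ratio of 3.98, so exact repeats are not the cause; copies with nearly equal counts were not removed by this. Scaled to total counts 1.98% against 0.49% were 2-fold lower, a ratio of 4.01, which argues against the choice between these scalings as the cause. A candidate explanation that stays open, and was not tested because the transcripts carry no gene names, is that these transcripts are RNAs held in particles other than tagged ribosomes.

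In mouse ES cells 5' leaders were higher against their own coding region with emetine. With the cycloheximide library thinned to the emetine depth the median difference was 0.42. Thinning lowers leader and coding reads at the same rate, so it cannot decide on depth. In leaders with 1000 or more reads the difference was 0.53, and the leaders' own median log2 ratio was 0.40 at 1000 to under 10000 reads. These values argue against low counts. More background reads outside reading frames with emetine stays open. Leaders with few reads per coding read showed a difference 0.23 larger than those with many. It met the bound of 0.2 set for background before that value was seen. This test cannot tell background from the lower emetine ratio of abundant coding regions, since coding reads enter both the grouping and the difference. A comparison chosen after the 0.23 was seen used another measure, the leaders' own log2 ratio grouped by leader reads. Leaders with 100 to under 300 reads and the 62 with 10000 to under 100000 reads differed by 0.00098 in its median. The 0.23 and the 0.00098 are therefore not directly comparable. A different placement of ribosomes by the 2 drugs may also account for the pattern and stays untested.

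In mouse ES cells coding regions with more reads had a lower emetine ratio. Between the lowest and highest bins the median log2 ratio differed by 0.63, and by 0.61 with the cycloheximide library thinned. Thinning removes reads from all features at the same rate, which leaves expected ratios as they were, so it cannot decide on depth. Trailers showed the same course, with a difference of 0.79 between the lowest bin and that of 10000 to under 100000 reads. Measured against their own coding regions, trailers with few and many reads per coding read differed by 1.23. Coding reads enter both that grouping and that measure, so it may partly restate the coding trend and is not separate support. More background reads with emetine may contribute to the lower ratio of abundant coding regions. Leaders, which also lie outside the main reading frame, showed no such course, with a difference of 0.00098. A drug effect that differs between abundant and rare messages is not excluded, and with 1 library per drug neither is a difference between the libraries themselves.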
